A study of Pseudomonas putida KT2440 with 6 samples.

How the data were processed

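Per the labels' protocols, Pseudomonas putida KT2440 was grown in 1 L baffled flasks with 100 mL of minimal medium and 40 mM glucose at 30 °C and 230 rpm from an optical density of 0.4. Pellets of 2 mg of cells were frozen, and RNA was extracted and labelled with Cy3 for 1-colour Agilent arrays. Per the labels, each biological replicate gave a control and a catechol sample, so the letters A, B and C pair the samples. Same-letter deviations from the group means correlated at 0.09, 0.10 and 0.00 across genes, which are not independent replicates; the pairing therefore rests on the design text.

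The deposited intensity values are spot signals of Agilent Feature Extraction, version 12.1.1.1 per the file headers, in which the processed signal is already corrected for background. The deposited flags of each spot (well above background, saturated, outlier), a unit of their own kind, come from the same software per the file headers. The authors also deposited log2 values per probe and per gene, whose making is not given in the sources used here. Differences between arrays of the authors' log2 probe values were set against those of the scanner values. They had slopes of 0.992 to 0.999 and offsets close to those of the 75th percentiles, so that the authors' scale is log2, shifted by array. A centring by probe cancels in such differences, so they cannot show it. The column medians of the authors' log2 probe values were 0.05, 0.03 and 0.01 for control A, B and C. For catechol A, B and C they were -0.08, 0.00 and -0.03. The authors' table of significant genes holds p-values and fold ratios that the file headers mark as averages. What was averaged and the test are not given in the sources used here. The number of per-sample columns that could not be mapped was 0.

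The array names genes by protein accessions, and the authors' tables name them by locus tag. The authors' gene values were equal to the means of their probe values to within a distance of 2.48e-07 over the 6 arrays, against a limit of 0.0001 and a nearest other gene at 0.0173, and 5237 of 5239 locus tags were joined to probes in this way. The gene table supplied for reference, of another assembly of the strain, held 0 of the array's accessions and 0 of the locus tags, so the files do not pair locus tags with symbols. Of 21 gene lists fixed before the data were examined, only the 3 written with locus tags could be used; the other 18, written as symbols, were not analysed here, nor was the part of the prophage list that rests on product names. The 18 symbols printed come from the tag and symbol pairs of these fixed lists, which rest on general knowledge of the strain. Named are all members of the catechol list, up to 3 members of every other list with the largest change among those past the threshold or else the member with the smallest adjusted p, and the loci with the largest changes that moved the same way in all replicates. The rule's demand for 8 risen and 8 fallen loci with an annotated name could not be met, and only 2 of each are given.

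Processed signals were taken to log2 and reduced by each array's 75th percentile over gene spots, which was 229, 289 and 285 for control A, B and C and 286, 272 and 299 for catechol A, B and C. Control spots and 864 to 935 outlier spots per array were left out. The 3 spots of a probe were averaged, then the probes of a gene (3 probes for 5194 genes, 2 for 42 and 1 for 2). Among called genes, 115 of 3127 had probes of both signs, none of them with both at least 2-fold. Genes with a probe well above background on at least 3 of 6 arrays were tested, which left out 299. For a gene not well above background in a whole group, a bound was taken from the higher, per array, of the gene's own level and the lowest level of any probe well above background.

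Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg, threshold 0.05), without a term for the pairs. Lists were tested with camera at a preset correlation of 0.01, and adjusted over 3 lists. Tables and figures used Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On data simulated for catechol against control with 4938 genes, 28% of changes of 0.5 log2, 78% of 1, 98% of 2 and 100% of 3 were called, with 7 calls among unchanged genes. The simulation changed only a small share of the genes, with independent noise of equal spread in both groups. These rates therefore need not hold for the data, where far more genes were called. Alternatives were the replicate block, normexp with an offset of 50, quantile, median and spike-in scaling, the authors' values, other filters, the brightest probe, a robust trended fit, treat against 1.5-fold, other set tests, and each array or pair left out. Because the files used hold no mean signal, normexp was run on the median signal and median background. Its offset of 50 is added to every signal, whereas array medians of the processed signal were 67 to 98. It therefore pulls log2 changes of dim genes toward 0 whatever their cause. All 6 arrays lay on 1 slide with 1 scan, control arrays in slide row 1 and catechol arrays in row 2, so slide row and group cannot be told apart.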

Results

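Transcript levels were measured in Pseudomonas putida KT2440, a soil bacterium that degrades many aromatic compounds, during growth on glucose in shake flasks. Each of 3 biological replicates, lettered A, B and C, gave 1 control sample before catechol was added, at an optical density of 2, and 1 sample taken 1 h after 5 mM catechol. Catechol is a toxic aromatic intermediate that this bacterium can cleave and use through the beta-ketoadipate pathway. The 6 RNA samples were hybridised to 6 one-colour arrays with 15668 probes, each printed in 3 spots. Between 84.0% and 87.1% of the 47004 gene spots of an array were well above background, and no gene spot was saturated. The number of arrays, 3 per group, limits the precision of every value below. No untreated culture at the later time was analysed here, so that catechol cannot be separated from the additional hour of growth. Expression levels are log2 signals relative to the 75th percentile of the same array.

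The comparison of catechol with control samples asked which genes had changed 1 h after the addition. Expression was altered across much of the genome: 3127 of the 4938 genes tested changed, 1337 being higher and 1790 lower after catechol (limma, adjusted p under 0.05). Of these, 693 were at least 2-fold higher and 458 at least 2-fold lower. Of 2 loci with large rises, which are not ranked here, PP_0105 was not well above background on any control array. After catechol it stood at -0.36 ± 1.37 (SD, n = 3), a measured log2 change of 6.19 (limma, adjusted p = 0.000491). With its control levels at their bounds, the change on the processed signal was at least 5.08 log2, or 33.8-fold, a bound that the adjusted p does not test. By replicate, this bound was 3.47, 5.95 and 5.82 log2 in A, B and C. PP_0806 rose from -2.43 ± 0.32 to 3.46 ± 0.93 (SD, n = 3 each), a log2 change of 5.89 ± 0.46 (SE, limma, adjusted p = 0.00025). With normexp background correction, whose offset of 50 pulls changes of dim genes toward 0, the log2 change was 2.24 for PP_0105 and 4.82 for PP_0806. The value for PP_0105 is below its bound, so the bound holds for the processed signal only. Large falls were those of PP_0362, with a log2 change of -5.03 ± 0.13 (SE, limma, adjusted p = 5.45e-05), and of PP_0363, with -4.20 ± 0.14 (SE, limma, adjusted p = 0.000128) and -2.71 with normexp. The 3 probes of PP_0363 ranged from -5.14, the brightest, to -2.95. All 4 loci moved in the same direction in each of the 3 replicates, and the files do not pair them with gene names.

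**Figure D1:**
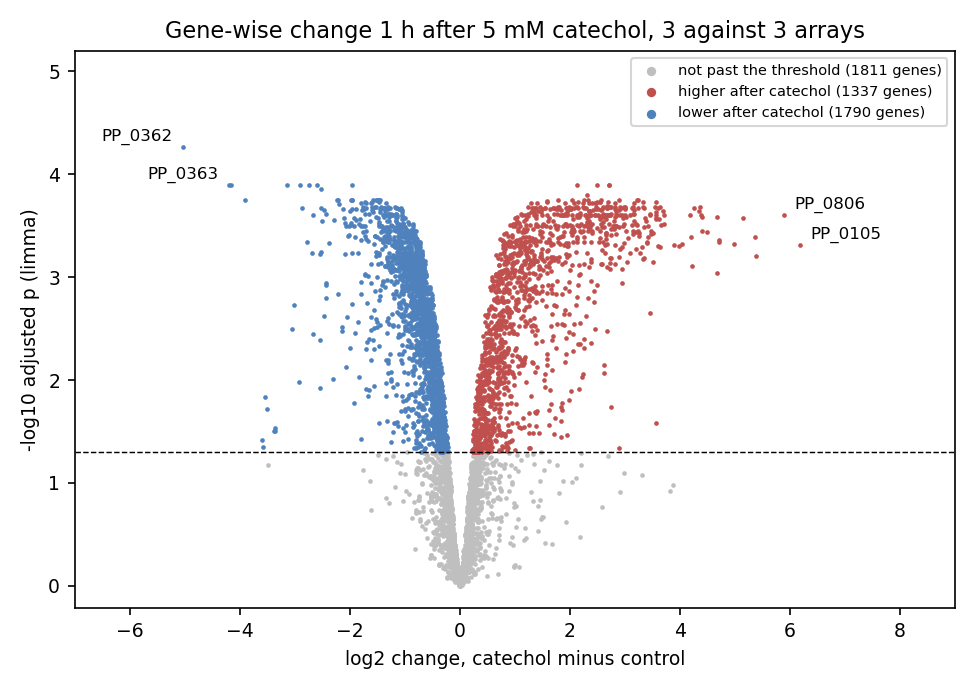
Log2 change of each of the 4938 genes tested (catechol minus control, x axis) against -log10 of its limma adjusted p (y axis), with 1 point per gene and a dashed line at an adjusted p of 0.05. Of the genes past the line, 1337 lie to the right and 1790 to the left, a balance that turned to 1851 and 879 with spike-in scaling; PP_0105, PP_0806, PP_0362 and PP_0363 are labelled, PP_0105 at its measured change although its control level is only a bound.

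The balance between higher and lower genes depended on the reference to which arrays were scaled. With arrays scaled to their spike-in spots in place of the 75th percentile, a choice made after seeing the data, 1851 genes were higher and 879 lower, and the median log2 change over all genes moved by 0.35. At least 2-fold, 1014 genes were then higher and 192 lower; these counts were 605 and 677 with median scaling and 372 and 201, together 573, with normexp background correction. The count of changed genes was 2038 without replicate B and 1870 without replicate C. The authors' deposited table of significant genes lists 1599 loci, 914 of them up and 685 down, with a fold of at least 2 and corrected p-values of up to 0.0498. Of the 1557 loci of the authors' deposited table that were tested here, 1498 were past the threshold, all 1498 in the direction of that table. Of these, 1150 were also at least 2-fold changed here.

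The genes for the cleavage of catechol and for the beta-ketoadipate pathway did not move as 1 group. Of the 9 members tested, 1 rose, 4 fell and 4 did not pass the test, with the same counts adjusted over the list alone (limma). pcaD (PP_1380), encoding the enol-lactone hydrolase of the pathway, rose from -1.67 ± 0.24 to -0.56 ± 0.09 (SD, n = 3 each), a log2 change of 1.11 ± 0.14 (SE, limma, adjusted p = 0.000832). pcaF (PP_1377), encoding the thiolase of the last step, fell with a log2 change of -0.74 ± 0.10 (SE, limma, adjusted p = 0.00105). catR (PP_3716), the regulator of the catechol genes, fell with a log2 change of -0.93 ± 0.16 (SE, limma, adjusted p = 0.00278). Its 3 probes disagreed, ranging from -1.97 to 0.08, and the brightest of them gave 0.08; with normexp it did not pass the test either, at -0.19 (limma, adjusted p = 0.117). pcaJ (PP_3952), encoding a subunit of the transferase that activates beta-ketoadipate, and pcaR (PP_1375), the regulator of the pca genes, fell with log2 changes of -0.41 ± 0.10 and -0.52 ± 0.16 (SE, limma, adjusted p = 0.0144 and 0.0272). The fall of pcaR was no longer past the threshold in the paired fit (limma, adjusted p = 0.0709), with its brightest probe (limma, adjusted p = 0.0739) or without replicate B (limma, adjusted p = 0.144). It was also lost without control A, B or C or catechol B (limma, adjusted p = 0.0832, 0.0626, 0.0501 and 0.072). That of pcaJ was lost with its brightest probe, at -0.19 (limma, adjusted p = 0.225), and without replicate B or C (limma, adjusted p = 0.159 and 0.0608). It was also lost without control B, control C or catechol B (limma, adjusted p = 0.0572, 0.0552 and 0.0507). With normexp the falls of pcaF, pcaJ and pcaR shrank to -0.23, -0.23 and -0.29 (limma, adjusted p = 0.0244, 0.0221 and 0.044), and with spike-in scaling they were not past the threshold (limma, adjusted p = 0.0564, 0.762 and 0.499).

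catA (PP_3713), encoding catechol dioxygenase, the ring-cleaving enzyme, stood at 5.35 ± 0.05 in the control and 5.64 ± 0.23 in the catechol samples (SD, n = 3 each), a log2 difference of 0.29 ± 0.13 (SE) that did not pass the test (limma, adjusted p = 0.0976). It passed with quantile normalization, at 0.81 (limma, adjusted p = 0.00472), with spike-in scaling, at 0.64 (limma, adjusted p = 0.0295), and without catechol replicate A, at 0.42 (limma, adjusted p = 0.00459). catC (PP_3714), encoding muconolactone isomerase, differed by 0.06 ± 0.08 (SE, limma, adjusted p = 0.511), a difference that was -0.10 with median scaling and passed the test with quantile normalization, at 0.32 (limma, adjusted p = 0.0114), and with spike-in scaling, at 0.41 (limma, adjusted p = 0.0355). pcaI (PP_3951), for the other transferase subunit, differed by -0.34 ± 0.20 (SE, limma, adjusted p = 0.188), and by 0.011 with spike-in scaling; it passed without catechol C, at -0.56 (limma, adjusted p = 0.0114). catB (PP_3715), encoding the muconate cycloisomerase, was not well above background on any of the 6 arrays and has no fold. catA2 (PP_3166), encoding another catechol dioxygenase, differed by 0.60 ± 0.82 (SE, limma, adjusted p = 0.548), with -0.91 in replicate A against 1.57 and 1.13 in replicates B and C. It passed without catechol replicate A, at 1.57 (limma, adjusted p = 0.00223), and was -0.015 without catechol replicate B. The list as a whole was not shifted against the other genes (camera, adjusted p = 0.641).

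None of the 8 genes for the uptake and oxidation of benzoate, which is converted to catechol, passed the test over all genes or adjusted over the list alone (limma), since the replicates went in opposite directions. Over the list, the median log2 difference was 2.70 in replicate B and 2.48 in replicate C, with all 8 genes higher after catechol, and -2.00 in replicate A, with all 8 lower. benA (PP_3161), encoding a subunit of benzoate dioxygenase, stood at 0.14 ± 0.88 in the control and 1.13 ± 3.78 in the catechol samples (SD, n = 3 each), with differences of -2.37, 2.71 and 2.62 in replicates A, B and C (limma, adjusted p = 0.658). benB (PP_3162) and benC (PP_3163), for other parts of the same dioxygenase, and benD (PP_3164), for the next step to catechol, gave differences of -2.02, -2.67 and -1.99 in replicate A against 2.62, 2.48 and 2.69 in replicate B. benK (PP_3165), encoding a benzoate transporter, and benF (PP_3168), encoding a porin, were well above background on 2 of the 3 catechol arrays. The array of replicate A was the other, so that their differences there are bounds, at most -2.35 and -0.73. Already before catechol, control A lay below controls B and C for 7 of the 8 genes, by 0.72 to 1.77 log2, the exception being benR. The regulator benR (PP_3159) had the smallest adjusted p of the list, with 0.65 ± 0.43 (SE, limma, adjusted p = 0.223), and benE (PP_3167) gave 1.55 ± 1.45 (SE, limma, adjusted p = 0.386). Except for benR, these genes were chosen after their values were seen. The list was not shifted against the other genes (camera, adjusted p = 0.508). Without catechol replicate A, but with control A kept, all 8 genes passed the test (limma). The list's median was then 3.08 (camera at the preset correlation, adjusted p = 0.00201). Without both arrays of replicate A all 8 were also higher, with a median of 2.58 (camera at the preset correlation, adjusted p = 0.000107). With all arrays, the correlation estimated for this list was 0.97, far above the preset one. These camera calls treat genes that moved together as nearly independent, so they do not decide whether the list was shifted.

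**Figure D2:**
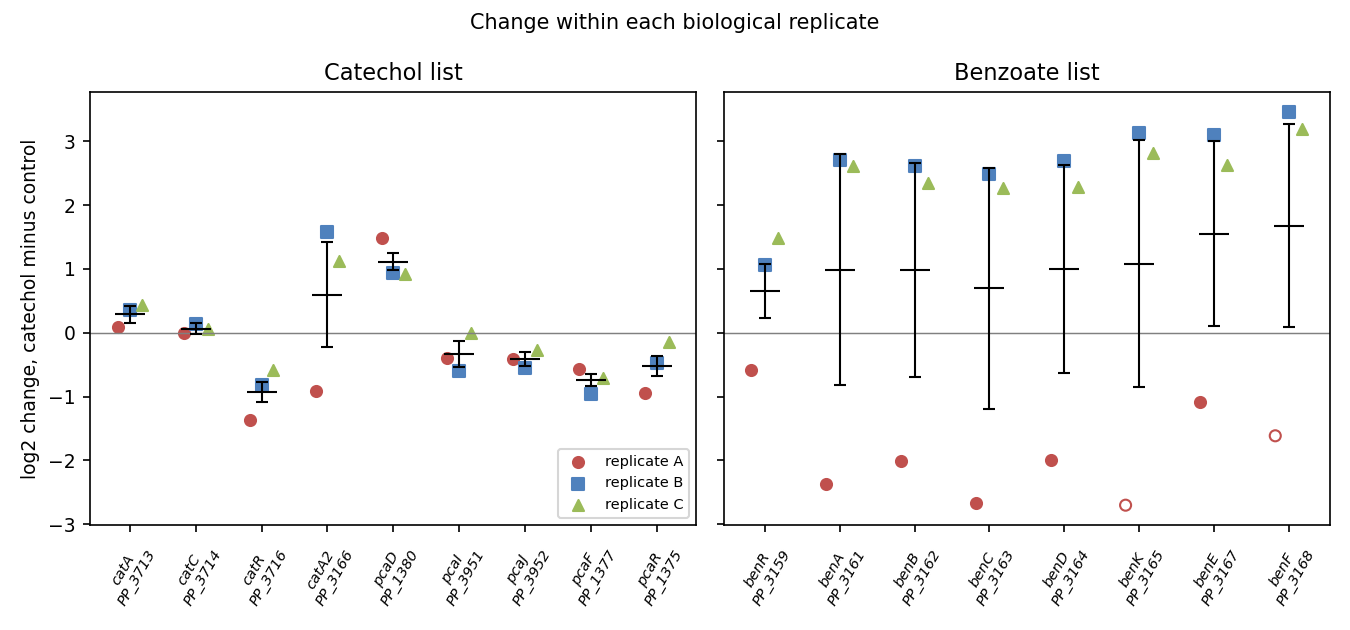
Log2 change (catechol minus control, y axis) of the 9 tested genes of the catechol list and the 8 genes of the benzoate list (x axis), with 1 marker per biological replicate and the mean with its limma standard error in black. Open markers stand for benK and benF in replicate A, whose catechol level was not well above background. The other benzoate genes of replicate A lie between -2.67 and -0.58, those of replicate B between 1.05 and 3.46 and those of replicate C between 1.48 and 3.19; the sign of the mean is turned for catC by median scaling, for pcaI by spike-in scaling and for catR by its brightest probe.

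Genes in the 4 prophage regions, stretches of viral DNA carried in the chromosome, were more often higher than lower. Of the 179 members tested, 72 rose, 19 fell and 88 did not pass the test (limma), and adjusted over the list alone 66 rose and 16 fell. The list was shifted upward against the other genes with a median log2 change of 0.27 (camera, adjusted p = 8.83e-05), a call that was lost with a correlation estimated from the data (adjusted p = 0.71 with an estimated correlation). The list's median was 0.12 with quantile normalization, 0.11 with median scaling, 0.62 with spike-in scaling and 0.17 without catechol B, and the list stayed shifted (camera, adjusted p = 0.00427, 0.00094, 1.3e-05 and 8e-04). Without the region from PP_1530 to PP_1586 the rest was still shifted (camera, adjusted p = 0.0169), but not with quantile normalization or median scaling (camera, adjusted p = 0.22 and 0.0872). The region from PP_1530 to PP_1586 held 36 of the risen genes and 4 that fell among 56, with a median of 0.49. This median was 0.22 with normexp, 0.36 with quantile normalization, 0.33 with median scaling and 0.84 with spike-in scaling, with 27, 31, 30 and 46 genes risen and 4, 5, 7 and 2 fallen. The region from PP_3849 to PP_3920 held 23 that rose and 7 that fell among 65, with a median of 0.30. With normexp these were 5 and 6, with a median of 0.0067, and with quantile or median scaling 15 and 10, with medians of 0.13 and 0.14. With spike-in scaling they were 46 and 4, with a median of 0.64. From PP_2266 to PP_2298, 6 rose and 5 fell among 26, with a median of -0.08 that was 0.26 with spike-in scaling, and 5 rose and 8 fell with quantile or median scaling, 4 and 4 with normexp and 11 and 3 with spike-in scaling. From PP_3026 to PP_3066, 7 rose and 3 fell among 32, with a median of 0.07 that was below 0 with median scaling, at -0.09, with quantile normalization, at -0.08, and with normexp, at -0.05. There, 4 rose and 4 fell with quantile or median scaling, and 0 rose and 2 fell with normexp, whereas 12 rose and 1 fell with spike-in scaling, with a median of 0.41. Large rises on the list were those of PP_2292, with a log2 change of 2.74 ± 0.33, PP_2291, with 2.53 ± 0.26, and PP_2290, with 2.39 ± 0.28 (SE, limma, adjusted p = 0.000723, 0.000453 and 0.000708), of which normexp left 2.61, 1.62 and 0.89. With normexp background correction 36 members rose and the list was not shifted (camera, adjusted p = 0.0569). Its median was then 0.00, against -0.08 over all genes. The count of risen members was 38 without replicate B and 37 without replicate C, and that of fallen members was 11 in both cases.

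**Figure D3:**
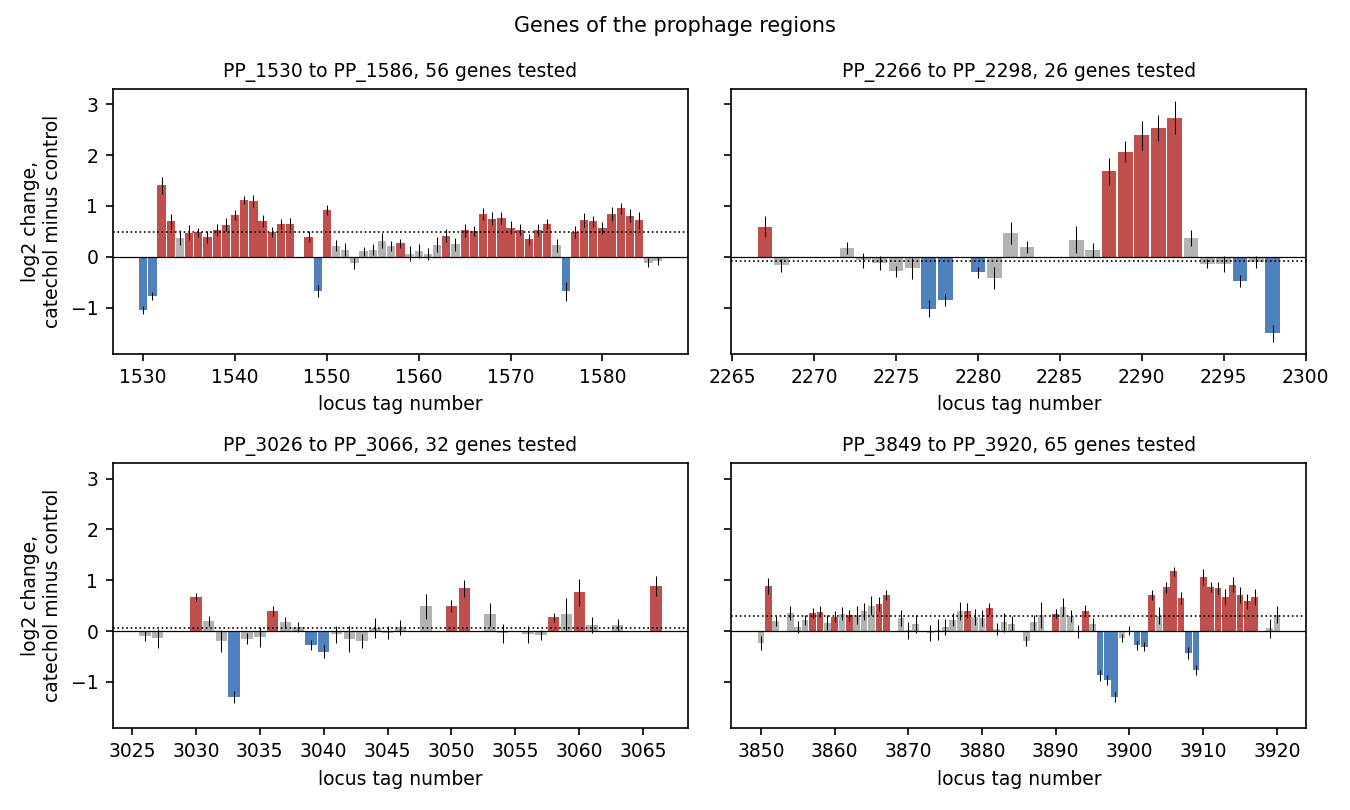
Log2 change (catechol minus control, y axis, bars from 0 with the limma standard error) of each tested gene of the 4 prophage regions by its locus tag number (x axis), in red where it rose, blue where it fell and grey where it did not pass the test, with the region's median dotted. The medians are 0.49, -0.08, 0.07 and 0.30 in the order of the locus tags; that of the region from PP_2266 turns to 0.26 with spike-in scaling, and that of the region from PP_3026 to -0.09 with median scaling, -0.08 with quantile normalization and -0.05 with normexp, with which that of the region from PP_3849 is 0.0067.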

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

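Spike-in scaling, treat for every result other than the count of changed genes, and all alternatives for the counts of each list were chosen after seeing the data. A block for slide or scan was not run, since the arrays share 1 slide and 1 scan. The replicate block (paired fit) called 2939 genes, 2868 of them shared with the unpaired fit, and among the named genes it ended only the call of pcaR.

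Against a 1.5-fold change 1119 genes were called (651 higher, 468 lower), by construction of that test. Under all other alternatives that kept the 6 arrays the count of changed genes lay within 1.5 times of 3127. The genes called differed more: of 2730 called with spike-in scaling, 2216 were shared with the unpaired fit. Shared genes were 2538 of 2568 with normexp and 2911 of 3156 with quantile normalization. Spike-in scaling, which moved every log2 change up by 0.35, gave 879 lower genes. Normexp gave 573 genes at least 2-fold changed. Its offset of 50 pulls changes of dim genes toward 0 by construction, and other causes were not tested. Scaling moved the median of all genes by 0.35 (spike-ins), -0.16 (median) and -0.12 (quantile). Of lists shifted, 1 in the unpaired fit, 0 remained with normexp and 0 with an estimated correlation. With fry, which does not set a list against the other genes, 1 list was called, the prophage list (fry, adjusted p = 0.0395). Catechol list genes higher numbered 3 with quantile normalization and 3 with spike-in scaling, and those lower 1 with the brightest probe, 0 against 1.5-fold and 1 with spike-in scaling. Prophage list genes higher numbered 36 with normexp, 11 against 1.5-fold and 115 with spike-in scaling, and those lower 29 with median scaling, 5 against 1.5-fold and 10 with spike-in scaling.

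With 1 array or 1 pair left out, changed genes ranged from 1870 (without replicate C) to 3713 (without replicate A). Higher genes ranged from 857 to 1718 and lower genes from 1013 to 1995. Lists shifted, by camera at the preset correlation, ranged from 1 to 2. Catechol list genes ranged from 1 to 3 higher and 2 to 5 lower, benzoate list genes from 0 to 8 higher, and prophage list genes from 37 to 93 higher and 11 to 19 lower. The direction of log2 differences turned within these ranges for benA (-0.15 to 3.17), benB (-0.11 to 2.99), benC (-0.49 to 2.96), benD (-0.067 to 2.97), benK (-0.18 to 3.43) and catA2 (-0.015 to 1.57), none of which passed the test with all arrays. It also turned for catC with median scaling (-0.10), for catR with the brightest probe (0.080) and for pcaI with spike-in scaling (0.011). Median and spike-in scaling moved the log2 change of every gene by 1 amount, -0.16 and 0.35, which turned catC and pcaI. The probes of catR disagreed, from -1.97 to 0.080, and why they did was not tested. catR was not past the threshold with normexp either, at -0.19 (limma, adjusted p = 0.117), and over all alternatives its adjusted p ran from 0.00076 to 0.613. Over the 24 named genes tested and all alternatives, 465 values kept their direction and side of the threshold, 21 kept the direction and lost the call, 25 gained a call and 14 turned. Treat against 1.5-fold ended the calls of catR, pcaJ, pcaF and pcaR. Signal close to background limits the values of dim genes such as PP_0105.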

Other observations

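Genes with consecutive locus tags changed together. Across genes, which are not independent replicates, the log2 changes of 4542 neighbouring pairs correlated at 0.507, and those of 4441 pairs 50 tags apart at 0.01 (permutation p = 1e-04, the smallest that 10000 shuffles can give, for the neighbours). There were 28 runs of at least 5 consecutive genes changed at least 2-fold in 1 direction, 18 higher with 120 genes and 10 lower with 71, against at most 2 such runs in 1000 shuffles of the gene order. The longest run held 25 genes, all lower after catechol. Neighbouring tags did not lie closer on the array than random pairs, the ratio of median distances being 1.01.

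Of the tests below, those of a control sample under a wrong label, of a weaker response, of the array's quadrants and of the scaling, and the repeats of the prophage tests under other scalings or normexp, were chosen only after the result was seen. Among the 10 splits of the 6 arrays into 3 and 3, 1 gave as many changed genes, the real one with 3127, and the highest of the others gave 0. The same held for the 4 splits that part all 3 pairs. These splits are too few for a share under 0.05.

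The benzoate genes were lower after catechol in replicate A and higher in replicates B and C, and all but benR were already lower in control A than in controls B and C, by 0.72 to 1.77 log2. A local defect of the array was tested on the spots of their 24 probes: the median SD over spots on catechol A was 1.81 times the highest of the other arrays (bootstrap 95% interval 1.14 to 2.74), which does not decide against the limit of 2 set in advance, but 66 of 70 spots were lower on catechol A than on control A, in all 4 quadrants of the array, with medians of -2.17 or below. A control sample under the catechol label is argued against by correlations over genes of at least 0.9555 with catechol B and C and at most 0.917 with a control. A weaker response of the whole sample would leave the list between 0 and the values of B and C, whereas its median in replicate A was -2.00, also with benK and benF, not well above background on catechol A, at their bounds. What stays open includes a difference between the cultures, and technical causes that touch a whole array or sample were not tested. Replicate A lay in slide column 1, B in column 3 and C in column 4, so slide column and replicate cannot be told apart. No biological explanation was tested.

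Of 1103 genes changed at least 2-fold in the same direction in replicates B and C, 1026 had that direction in replicate A too, and 19 were opposite and at least 2-fold, 7 of them on the benzoate list; with levels not well above background at their bounds these were 18 and 6. Across genes, the changes of replicates B and C correlated at 0.970, and those of replicate A correlated at 0.790 with their mean.

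Among all changed genes, more were lower than higher with the 75th percentile. Among those changed at least 2-fold more were higher, 693 against 458. The share of higher genes among all changed genes was 42.8%, against 67.8% with spike-in scaling, 37.7% with quantile normalization and 33.6% with median scaling. Each reference of the 75th percentile, median and spike-in scalings shifts all genes of an array by 1 amount. No value here says which is right, so the balance stays undecided. The balance also differed by signal level, with the genes put into 5 groups by mean level. The median log2 change was 0.11 in the dimmest group, with 272 genes higher and 174 lower. It was 0.02, -0.03 and -0.25 in the next groups. In the brightest group it was -0.38, with 188 genes higher and 519 lower. A shift by 1 amount per array cannot remove such a trend, and its cause was not tested. The 75th percentile relative to the spike-ins was -3.53 ± 0.08 in the control and -3.18 ± 0.14 in the catechol arrays (SD, n = 3 each; exact permutation test, 2-sided, p = 0.1, the smallest that 3 against 3 can give). No biological explanation, such as a change in the RNA content of the cells, was tested.

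The prophage list was shifted upward with a median of 0.27, and no explanation tested could be ruled out. The median lay at percentile 99.34 of blocks of neighbouring genes placed at random. This percentile was 98.28 with quantile normalization. Median and spike-in scaling move every gene's change by 1 amount, so their 99.34 is the same result by construction. With normexp the percentile was 93.06, so neighbours that move together stay open. With 1 region left out in turn the highest camera adjusted p was 0.0169 (without PP_1530 to PP_1586), but without that region it was 0.763 with normexp, 0.22 with quantile normalization and 0.0872 with median scaling, against 0.00114 with spike-in scaling, so 1 region as the whole cause stays open. Low signal stays open: the median lay at percentile 100.00 of random lists matched on level, but these share the background correction. With normexp the list's median was 0.00, against -0.08 over all genes, and the call was lost. The offset of normexp pulls changes of dim genes toward 0 whatever their cause, so this loss cannot decide the question. With an estimated correlation the list was not shifted (camera, adjusted p = 0.71), and no biological explanation was tested.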
